A study of Mus musculus with 2 samples.

How the data were processed

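Total RNA was measured by sequencing in the adrenal gland of female mice of the B6CASTF1/J strain, an F1 hybrid with a CAST parent, at 25 days of age. There were 2 libraries in 1 group, named replicate 1 and replicate 2 after the biological replicate number in the labels. Per the labels, each library started from 300 ng of RNA, was made with a directional kit and held ERCC spike-ins, synthetic RNAs added in a known mixture. The amounts of the spike-ins were not used here. The labels differ on the source of the libraries: the descriptions of the tissue give separate animals, while the library description and the donor field are the same for both. Whether the libraries came from separate animals therefore stays open. Every SD measures only the spread between these libraries, which may be technical. The tests set the difference between these libraries against counting error and hold no estimate of that spread.

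For each library 3 tables were used. The gene table and the first transcript table come from the same quantification. The second transcript table comes from another quantification, and its values were summed per gene for comparison. Per the notes deposited beside the files, the reads were quantified against mouse genome build mm10 with GENCODE M21. The program and its version are not given in the sources used here. The authors deposited expected counts, which are estimated reads per gene or transcript and need not be whole. The deposited TPM values are scaled to a fixed sum over all features, so that spike-ins, mitochondrial genes and ribosomal RNA take part of the sum. The deposited FPKM values are, within a library, a constant multiple of TPM. The first transcript table also gives, per the file headers, the percent of a gene's abundance on each transcript. All 55536 annotated genes in the gene table were matched by identifier to the GENCODE M21 annotation, from which symbols, gene types and coordinates were taken. The table also held 26248 tRNA entries and 97 spike-in entries.

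Expected counts summed to 19366343 in replicate 1 and 33728646 in replicate 2. The nuclear protein-coding genes other than Lars2 received 7038809 and 22306477 of them, so coding genes were measured with fewer reads in replicate 1. Levels are deposited TPM, as mean ± SD (n = 2). Ratios between the libraries are log2 of replicate 2 over replicate 1, from expected counts scaled by TMM (edgeR 4.0.16, R 4.3.3) with a prior of 1 count. Counts were rounded to whole numbers for the tests and for TMM. Ratios of counts and of TPM can differ for genes with several transcripts, since TPM depends on how reads were split among transcripts of different length. A further scale, called coding TPM, scaled TPM to the same fixed sum over nuclear protein-coding genes other than Lars2. It was chosen after the data were seen.

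With 1 group no test between groups exists. Levels of different genes were compared in both libraries without a p-value, since 2 values against 2 allow a two-sided exact permutation p of 0.333 at the lowest. A chi-square test compared the rounded counts of both libraries over genes with a summed count of at least 10. An exact conditional binomial test with Benjamini-Hochberg adjustment was run per gene at a mean count of at least 100. Both tests compare these libraries only and cover counting error only. So do the intervals of folds and of spike-in shares, which are exact Clopper-Pearson intervals at 95%. Bootstrap intervals of a list median resample its genes and show the spread among them. Upper bounds of tissue median counts are Poisson limits applied to the median. Reads without molecular identifiers are not independent molecules. Where a gene had 0 counts in a library, its fold is given as the limit of its Clopper-Pearson interval or not at all, and 3 counts served as the floor. For each gene list the median log2 ratio was set against 10000 random lists of the same size, each member being replaced by a gene drawn from the 200 nearest in mean expression. The percentile describes these libraries. The computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

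The log2 ratios, the adjusted binomial test, the chi-square test and the list percentiles were tested on simulated data. The other steps, TMM among them, were not. Poisson counts were drawn for the real genes, and 200 genes were changed. Apart from these genes both simulated libraries had the same composition, and they were scaled by total counts. The draws held no spread beyond counting error and no genes that vary together, so the rates below apply only without these. Of the changed genes tested among 11365 genes, the binomial test found 83.7% at 1.5-fold and 100% at 2-fold, 4-fold and 8-fold. Of the genes changed 2-fold, 59.6% came out at 2-fold or more. Of the 11182 unchanged genes it called 0.063%. For 2 draws from the same library the chi-square statistic was 0.99 times its degrees of freedom. Of 100 random lists of 10 genes, 6 lay outside the middle 95%.

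The 27 gene lists, the planned tests and the rule for named genes were fixed before the data were examined. The chi-square over nuclear protein-coding genes other than Lars2 was added after the data were seen. The text names the 10 nuclear protein-coding genes with the highest mean TPM, up to 4 members of each list with the highest mean TPM, and members under 1 TPM in both libraries where their absence is counted. All members of the steroidogenic core, zona glomerulosa, X-zone, chromaffin cell, X-inactivation and Y-linked lists may be named. The rule adds the 10 protein-coding genes with the largest ratio in each direction at a mean count of at least 100. Where a gene falls outside this rule, the text says that it was chosen after its values were seen. Genes with near-identical copies are reported as uncertain. Some list members count in the list medians and totals, but their own values are not reported here. The alternatives tried were DESeq2 1.42.0 size factors, total counts and spike-in counts for scaling, other count minimums, thresholds, pseudocounts and prior counts, FPKM, posterior mean values, the second quantification and each library alone.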

Results

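Adrenal glands of female B6CASTF1/J mice aged 25 days were profiled by total RNA sequencing in 2 libraries, replicate 1 and replicate 2, which form 1 group. The data describe which genes the gland expressed, how its cortical, medullary and other cell types were represented, and how closely the libraries matched. Expected counts summed to 19366343 in replicate 1 and 33728646 in replicate 2. Only the libraries themselves could be compared, as the design holds no other group.

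The libraries differed in the RNA classes that took the reads. Nuclear protein-coding genes other than Lars2 held 36.4% of the counts of replicate 1 and 66.1% of those of replicate 2. Gm42418, a transcript on chromosome 17 (39846958 to 39848788, mm10) that lies within the annotated ribosomal RNA gene CT010467.1 on the opposite strand, held 24.2% in replicate 1 and 0.605% in replicate 2. Mitochondrial ribosomal RNA held 23.1% and 11.6%. The signal recognition particle RNAs Rn7s1 and Rn7s2 held 2.35% and 5.37% of counts and, being short, 13.8% and 28.6% of TPM, while the second quantification gave them 9983 and 6 counts. Deposited TPM of coding genes summed to 206815 in replicate 1 and 338304 in replicate 2, and the SDs of TPM include that difference in scale. It can widen an SD or hide a difference between the libraries, so a small SD of TPM need not mean close libraries.

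Gm42418, CT010467.1, Rn7s1, Rn7s2 and the gene copies Hspa1a and Gm10925 were picked for naming after their values were seen.

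**Figure D1:**
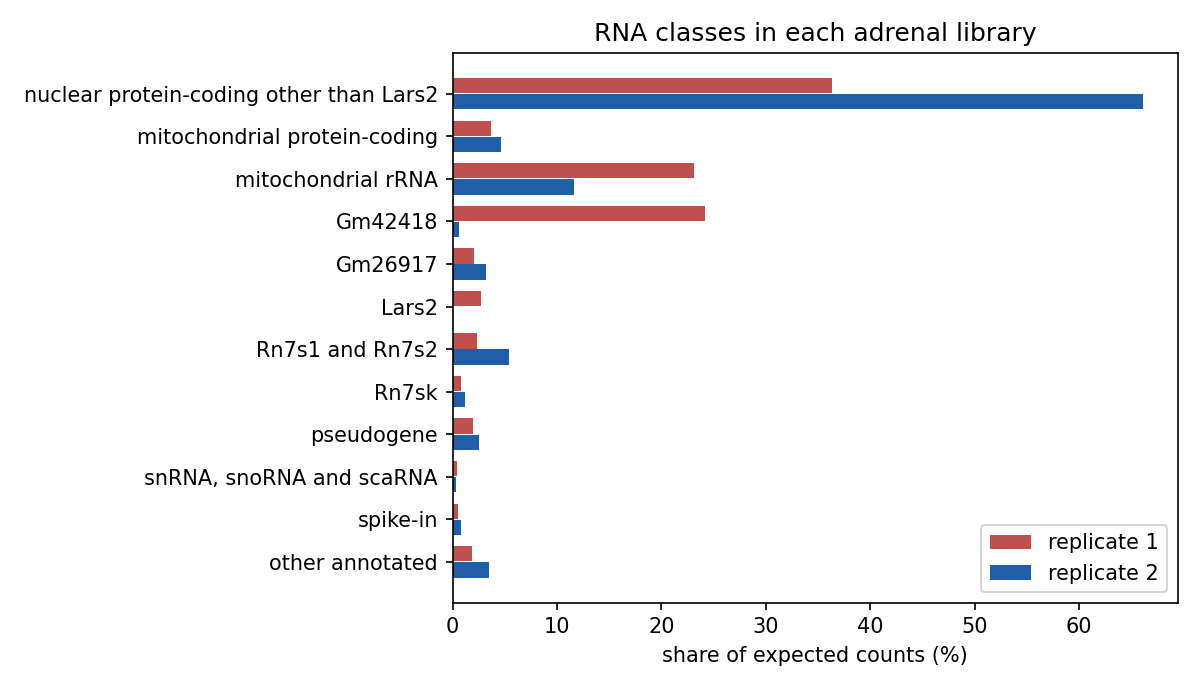
Bars give the share of expected counts (%) in each RNA class, for replicate 1 in red and replicate 2 in blue. Gm42418 held 24.2% in replicate 1 and 0.605% in replicate 2, and nuclear protein-coding genes other than Lars2 held 36.4% and 66.1%.

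At a threshold of 1 TPM, 12705 annotated genes were detected in replicate 1, 13992 in replicate 2 and 12460 in both, of which 11352 were protein-coding. Enzymes and carriers of steroid synthesis were among the most abundant nuclear coding genes. Hsd3b1, which converts pregnenolone to progesterone, reached 4375 ± 1955 TPM (SD, n = 2), and Star, which brings cholesterol into mitochondria, reached 3492 ± 1437 TPM. Akr1c18, a progesterone-degrading enzyme of the X-zone, followed at 2080 ± 852 TPM. The translation factor Eef1a1 was at 2005 ± 174 TPM, the alcohol dehydrogenase Adh1 at 1965 ± 616 TPM and the matrix protein gene Sparc at 1003 ± 391 TPM. The steroid hydroxylase genes Cyp21a1, Cyp11a1 and Cyp11b1 were at 1870 ± 854, 1861 ± 671 and 1261 ± 451 TPM. On the coding TPM scale, which removes the difference in RNA classes, Hsd3b1 was at 15740 ± 1802, Star at 12650 ± 958 and Cyp11a1 at 6803 ± 141. Lars2, a mitochondrial leucyl-tRNA synthetase, had the highest mean, 4459 ± 6274 TPM, which rested on replicate 1 alone (8896 against 22.4 TPM). In replicate 2 alone it was far below the other genes named here. Of its 9 annotated transcripts, 1 of the nonsense-mediated decay type led in both libraries. In replicate 1 that transcript held 99.57% of Lars2 TPM in the first transcript table and 99.96% in the second. In replicate 2 it held 51.38% and 42.82%. The high mean of Lars2 is thus mostly that of this transcript, and whether its reads came from Lars2 messenger RNA was not tested.

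All 14 members of the steroidogenic core list were detected in both libraries. The list median was 431 ± 95.6 TPM (n = 2). On the TMM scale its median log2 ratio between the libraries was 0.01, at percentile 87.1 of random lists. Hsd3b1 (chromosome 3, 98852194 to 98859794), Star (chromosome 8, 25806555 to 25815982), Cyp21a1 (chromosome 17, 34801348 to 34804561), Cyp11a1 (chromosome 9, 58006411 to 58027023) and Cyp11b1 (chromosome 15, 74834125 to 74841643) had ratios of 0.20, -0.20, 0.22, 0.01 and 0.00. The lipoprotein receptor Scarb1 stood at 600 ± 77.2 TPM, ferredoxin Fdx1 at 490 ± 62.2 TPM and the transcription factor Nr5a1 at 197 ± 88.1 TPM. The corticotropin receptor Mc2r was at 75.7 ± 28.8 TPM. Its accessory protein Mrap was at 135 ± 9.55 TPM and had the lowest ratio of the list, -0.91.

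Markers of the cortical zones were present at very different levels. In the zona glomerulosa list, the outer zone that makes aldosterone, all 8 members were detected in both libraries, with a median of 21.5 ± 5.81 TPM. Dab2 led at 119 ± 24.8 TPM, followed by Agtr1a at 49.5 ± 0.0919, Cyp11b2, the aldosterone synthase, at 39.9 ± 19.3 and Wnt4 at 24.8 ± 9.91 TPM. Despite its small SD, Agtr1a had a ratio of -0.87, with coding TPM of 239.8 in replicate 1 and 146.2 in replicate 2. Cyp11b1 exceeded Cyp11b2 by 32.7 ± 4.52 times, in both libraries (35.9 and 29.5). These neighbouring paralogs can share reads: the ratio of Cyp11b2 between the libraries was 0.28 in the first quantification and -0.20 in the second. The zona glomerulosa median ratio was -0.25, at percentile 0.36. In the zona fasciculata list, the zone of glucocorticoid synthesis, all 6 members were detected, with a median of 282 ± 10.8 TPM and a median ratio of -0.14, at percentile 14.8. In coding TPM the list median was 1400 in replicate 1 and 810.6 in replicate 2. Abcb1b was at 659 ± 266 TPM, with a ratio of -0.08, and Akr1b7 at 428 ± 12.1 TPM, with a ratio of -0.80.

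The X-zone, an inner cortical layer of young mice, was represented by 3 of its 4 list members. The list median was 38.1 ± 18.9 TPM, with a median ratio of 0.17 at percentile 92.6. Akr1c18 (chromosome 13, 4132615 to 4150654) stood at 1477 TPM in replicate 1 and 2682 TPM in replicate 2, Pik3c2g at 47.5 ± 20.1 TPM and Thrb at 28.7 ± 17.7 TPM. Cyp17a1, the 17-alpha-hydroxylase, was under the threshold at 0.39 TPM in both libraries, from 12 and 15 counts.

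**Figure D2:**
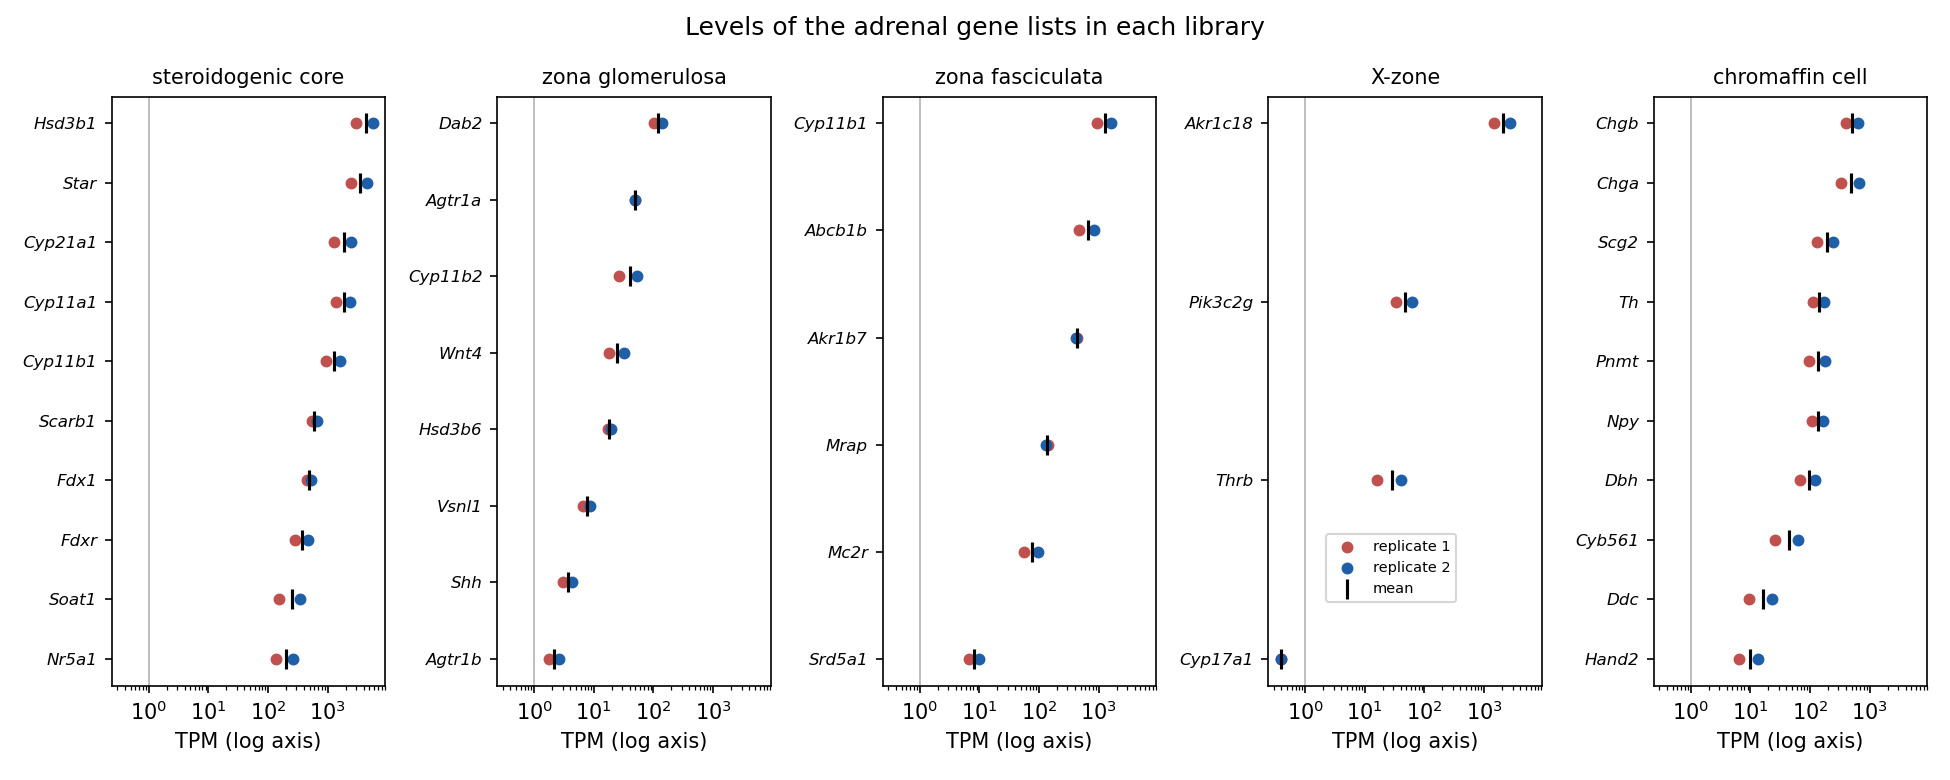
Points give the TPM (log axis) of up to 10 members with the highest mean in each of 5 adrenal gene lists, in replicate 1 (red) and replicate 2 (blue), black ticks the mean, and grey lines 1 TPM. Hsd3b1 reached 4375 TPM on average and Cyp17a1 0.39 TPM.

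Chromaffin cells of the medulla, which make catecholamines, were represented by 17 of 18 list members at or above 1 TPM in both libraries. Ret was under it in both, at 0.46 and 0.97 TPM. The granins Chgb (513 ± 162 TPM), Chga (496 ± 225 TPM) and Scg2 (190 ± 79.1 TPM) were the most abundant. Tyrosine hydroxylase Th was at 141 ± 40.5 TPM, Pnmt, which turns noradrenaline into adrenaline, at 138 ± 59.3 TPM, and Dbh at 95.5 ± 38.8 TPM. Star exceeded Th by 24.2 ± 3.22 times. The list median was 13.1 ± 7.24 TPM. Of the 18 members 15 had a higher scaled count in replicate 2, and the median ratio of 0.25 stood at percentile 100. Phox2a, a transcription factor of these cells, had the highest ratio (0.77). On the spike-in scale 17 of 18 were higher.

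Stromal, vascular and immune markers ranged from detected throughout to not detected. In the capsule and fibroblast list 8 of 10 members were detected in both libraries, with a median of 12.98 ± 4.21 TPM, led by Col3a1, a fibrillar collagen gene, at 37.3 ± 5.996 TPM and Nr2f2 at 28.9 ± 6.19 TPM. Its median ratio was -0.20, at percentile 1.96. All 9 endothelium members were detected, with a median of 15.1 ± 6.50 TPM and a ratio of 0.11 at percentile 91.7, and Plvap, a protein of fenestrated capillaries, led at 49.1 ± 19.9 TPM. In the Schwann and sustentacular list 3 of 7 members passed the threshold, led by Mbp (3.14 ± 1.98 TPM) and S100b (3.09 ± 0.884 TPM), with a list median of 0.645 ± 0.0495 TPM and a ratio of 0.25 at percentile 75.3. Of 8 macrophage genes 6 were detected in both libraries, with a median of 4.96 ± 1.64 TPM and a ratio of 0.28 at percentile 95.7. C1qb was at 7.22 ± 2.98 TPM. None of the 7 lymphocyte genes reached 1 TPM in either library. The list median was 0.095 ± 0.0778 TPM. The percentile of its ratio, 75.8, rested on 19 counts or fewer per gene and library.

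Blood and fat transcripts were abundant. All 5 erythroid genes were detected, with a median of 514 ± 79.1 TPM and a ratio of -0.15 at percentile 7.63, which was 0.61 in the second quantification. The globins Hba-a1 (596 ± 181 TPM) and Hba-a2 (554 ± 22.03 TPM) are near-identical copies, so the split between them is uncertain. In the adipocyte list 7 of 8 members were detected in both libraries, with a median of 61.6 ± 13.8 TPM. The fatty acid carrier Fabp4 was at 457 ± 90.7 TPM, the brown fat uncoupling protein Ucp1 at 175 ± 14.3 TPM, Plin1 at 87.8 ± 31.4 TPM and Cidea at 84.7 ± 10.9 TPM. The median ratio was -0.32, at percentile 0.22, with Ucp1 at -0.91. On total counts 7 of its 8 members were higher in replicate 2.

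Of the 3 lists of other organs, liver alone lay outside the random lists. None of the 8 kidney genes reached 1 TPM, and the list median was 0.02 ± 0.0141 TPM. Most kidney genes had 3 counts or fewer in both libraries, so that the percentile of 38.6 says little. Of the 7 exocrine pancreas genes Cela1 alone was detected, at 15.7 ± 5.03 TPM. That list had a median of 0.04 ± 0.0566 TPM, and its percentile of 53.8 likewise rested on counts near the floor of 3. The liver list differed: its median was 22.1 TPM in replicate 1 and 0.17 TPM in replicate 2, and all 7 members had a lower scaled count in replicate 2. The median ratio was -6.99, at percentile 0. Alb, serum albumin, stood at 141 TPM (4477 counts) in replicate 1 and 3.47 TPM (73 counts) in replicate 2. Its scaled count was 197-fold higher in replicate 1 (95% counting interval 156 to 252). Cyp2e1 was close in TPM, at 40.9 and 38.2, and on total counts it was the member that did not lie lower in replicate 2.

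Imprinted genes, which are read mainly from a single parental copy, were well represented. Of 9 maternally expressed genes 8 were detected, with a median of 22.8 ± 7.06 TPM and a ratio of -0.03 at percentile 41.1. Meg3 (271 ± 113 TPM), Cdkn1c (219 ± 111 TPM) and Rian (151 ± 51.3 TPM) led, and Phlda2 was under 1 TPM at 0.575 ± 0.0212. Of 13 paternally expressed genes 12 were detected in both libraries, with a median of 8.34 ± 2.66 TPM and a ratio of 0.02 at percentile 57. Dlk1 was at 169 ± 62.8 TPM and Peg10 at 120 ± 9.77 TPM. The tables hold no counts per parental allele. Xist, the RNA of the inactive X chromosome, was at 67.8 ± 11.7 TPM, and its antisense gene Tsix at 0.275 ± 0.205 TPM. The median of this pair was 34.1 ± 5.96 TPM, with a ratio of 0.41 at percentile 89.7. None of the 4 Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y had over 2 counts in either library, below the floor of 3. A count of 0 still allows up to 3 counts of a library. Their median was 0.0025 ± 0.00354 TPM. The percentile of 52.7 rested on these counts.

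Lists of cell state differed in how far the libraries lay apart. All 17 cholesterol synthesis genes were detected, with a median of 41.5 ± 7.59 TPM, and all 17 had a lower scaled count in replicate 2 under TMM, 13 of 17 on the spike-in scale and 0 of 17 on total counts. Their median ratio was -0.28, at percentile 0. Dhcr7 (325 ± 72.7 TPM), Fdps (226 ± 66.6 TPM) and Hmgcs1 (171 ± 13.7 TPM) were the most abundant. All 10 proliferation genes were detected at a median of 5.31 ± 0.279 TPM. Their median ratio was -0.47, at percentile 0, and 9 of 10 were lower in replicate 2 under TMM, 8 on the spike-in scale and 0 on total counts. Among them were Pcna (-0.26), Mcm2 (-0.34) and Top2a (-0.40). In the interferon response list 4 of 8 members were detected in both libraries, with a median of 2.06 ± 1.20 TPM and a ratio of 0.48 at percentile 99.7. Of 13 immediate early and heat shock genes 10 were detected, with a median of 7.11 ± 0.311 TPM and a ratio of 0.09 at percentile 80.3. Jun stood at 33.8 ± 14.0 TPM and Nr4a1 at 31.9 ± 15.8 TPM. Hspa1b, whose reads can be shared with its copy Hspa1a, had a ratio of -1.55. Of 13 circadian clock genes 12 were detected, with a median of 11.3 ± 4.84 TPM and a ratio of -0.10 at percentile 10.6. Dbp was at 103 ± 61.4 TPM, with a ratio of 0.67.

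Among abundant non-coding RNAs all 8 were detected, with a median of 2738 ± 1285 TPM and a ratio of -0.08 at percentile 38.2. The second quantification gave a median of 131.7 TPM and percentile 0.08. Rn7sk reached 48160 ± 8269 TPM, Rmrp, summed over its 2 gene identifiers, 7157 ± 901 TPM, Rpph1 5794 ± 2419 TPM and Malat1 5136 ± 2410 TPM. Of 13 mitochondrially encoded genes 12 were detected in both libraries, with a median of 4419 ± 172 TPM and a ratio of -0.66 at percentile 0, while its median was 0.22 on total counts. mt-Co2 was listed at 0 counts in replicate 1, though the second quantification gave it reads in both libraries. mt-Co1 led at 9318 ± 1678 TPM. mt-Atp6 is uncertain because the nuclear pseudogene Gm10925 shares its sequence: its ratio was 2.49 alone and -0.32 for the summed counts. The 8 housekeeping genes had a median of 301 ± 87.2 TPM and a ratio of -0.03 at percentile 53.0, with Actb at 823 ± 318 TPM and a ratio of 0.04.

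**Figure D3:**
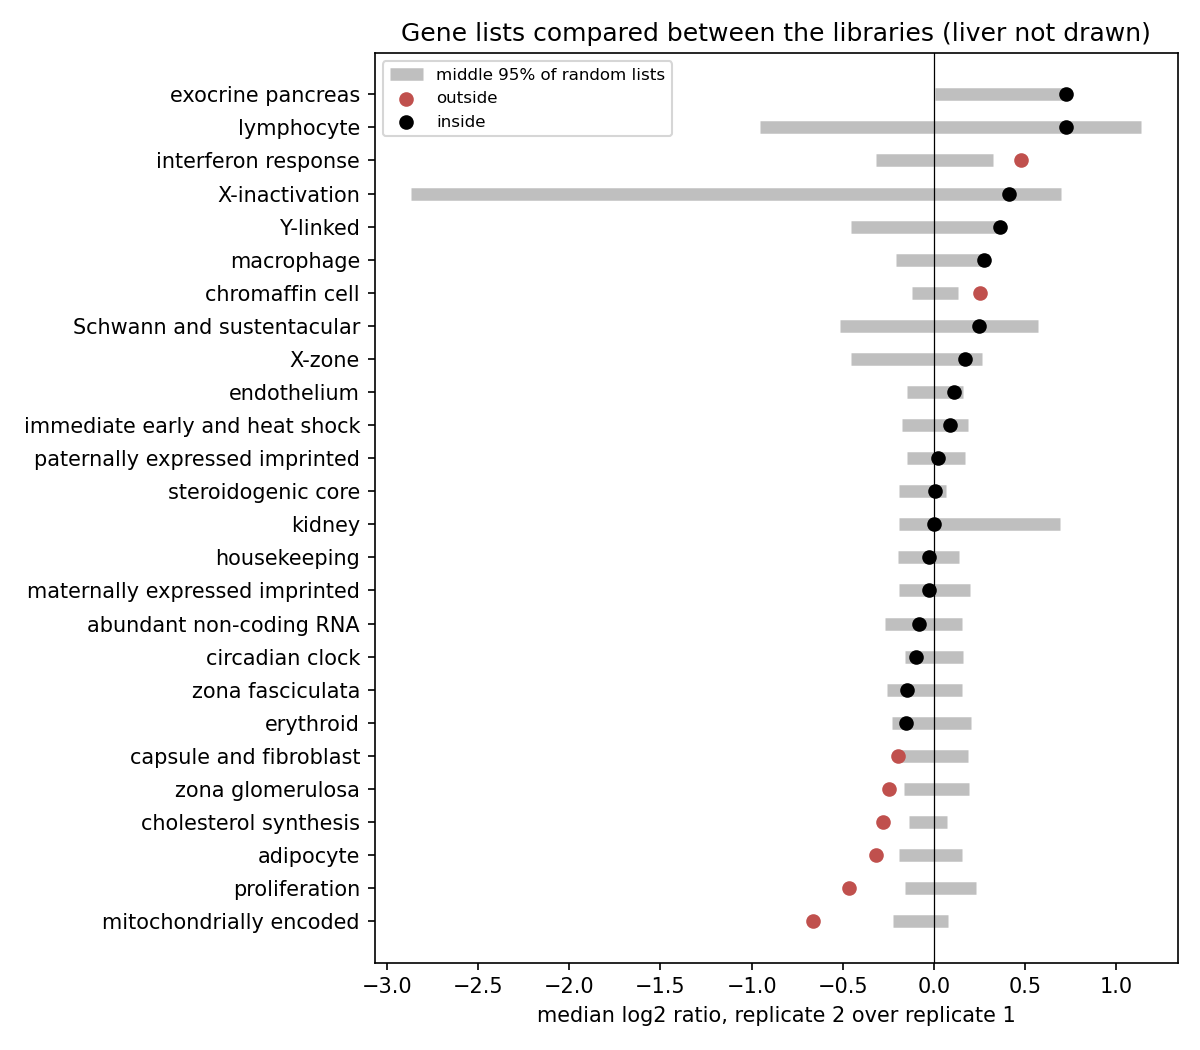
Points give the median log2 ratio of replicate 2 over replicate 1 for 26 gene lists, and grey bars the middle 95% of 10000 random lists matched on expression. Medians outside the bars are red, and the liver list, at -6.99, is not drawn.

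Over all lists, 9 of 27 lay outside the middle 95% of random lists, 7 below and 2 above. For lists of unrelated genes 1.35 would be. Members of these lists can vary together, and some lists share genes, so 1.35 is not the number due by chance here. Across 14237 genes at or above 1 TPM in either library, log2(TPM + 1) correlated at Pearson 0.958 and Spearman 0.961. Genes are not independent replicates. The libraries differed by more than counting noise, with a chi-square of 653 times its degrees of freedom over 18662 genes, and 14.5 times over the 14788 nuclear protein-coding genes other than Lars2. Of 11542 genes with a mean count of at least 100, 152 (1.32%) were 2-fold or more apart, 45 higher and 107 lower in replicate 2. The exact binomial test with Benjamini-Hochberg adjustment called 3870 genes, the 152 included. The median absolute log2 ratio was 0.16. The median log2 ratio of all 11542 genes was 0.03 under TMM, 0.16 on the spike-in scale and 0.92 on total counts, and list ratios are relative to it. The median of 12 of the 27 lists, among them 6 of the 9 outside the random lists, had another sign on total counts than under TMM, and of 4 on the spike-in scale. On the spike-in scale the split was 80 higher and 85 lower, and on total counts 4132 higher and 36 lower. With a minimum of 10 counts it was 458 higher and 480 lower, and with no minimum 2778 and 2234.

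**Figure D4:**
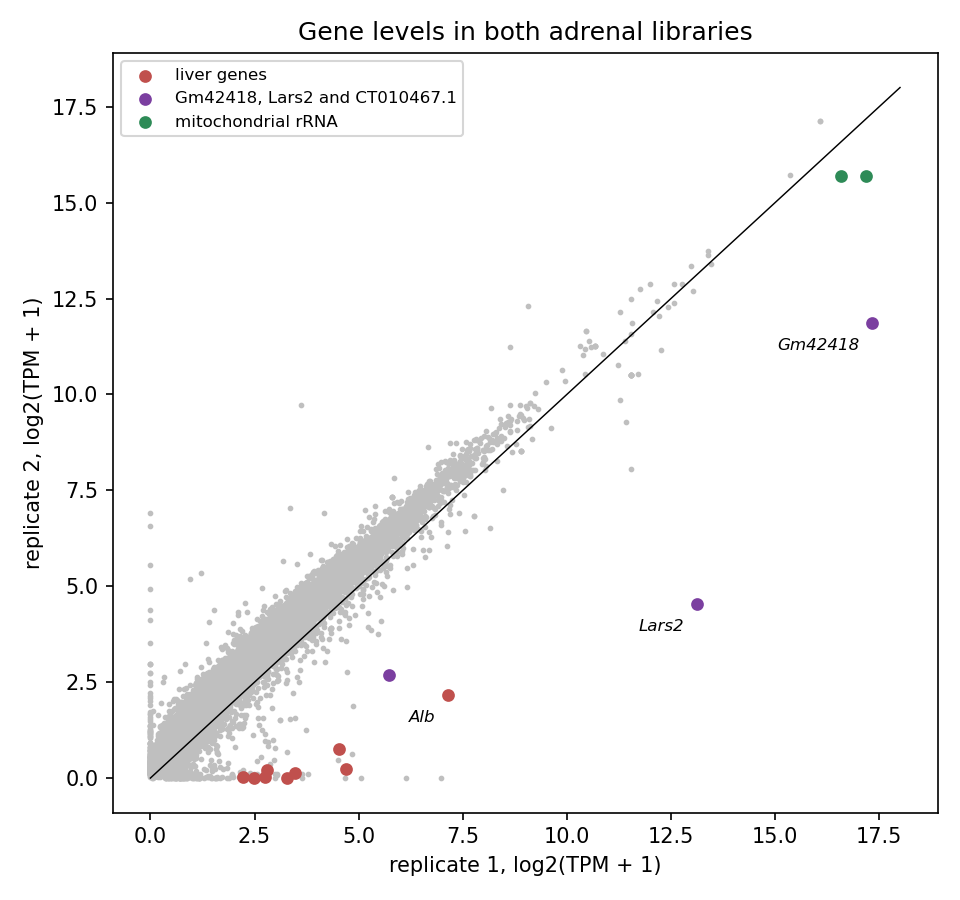
Each point is a gene with a summed count of at least 10, with log2(TPM + 1) in replicate 1 on the horizontal and in replicate 2 on the vertical axis, and the line marks equal values. Alb, at 141 and 3.47 TPM, and Gm42418, with 24.2% and 0.605% of counts, lie below the line.

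The 10 coding genes with the lowest ratio were Lars2 (-9.39), Cps1, Gc, Apob (-8.35), Fgb, Alb (-7.59), Apoa1 (-7.54), Serpina1b (-7.53), Pzp (-7.19) and Fga (-7.16). All but Lars2 encode products made mainly by the liver, and all 10 were also 2-fold or more lower in replicate 2 in the second quantification. Gc had 228 counts in replicate 1 and 0 in replicate 2. Its scaled count was at least 197-fold higher in replicate 1 by the limit of its 95% counting interval, and 140-fold in the second quantification, with 248 and 4 counts. In scaled counts Cps1, with 413 counts and 1 count, was 1330-fold higher (95% counting interval 237 to 52500), and Fgb, with 223 and 2 counts, 358-fold (98.0 to 2980). The 10 with the highest ratio were mt-Co2 (0 and 2204.55 counts), Hist1h2ap (4.40), mt-Atp6 (2.49), Gm14288 (2.46), Tmem254c (2.36), Gvin1 (2.23), Lep (1.87), Zbtb7c (1.66), Ajap1 (1.62) and Rpl10 (1.54). Of these, 5 kept the direction at 2-fold or more in the second quantification, namely Gm14288, Gvin1, Lep, Zbtb7c and Ajap1. The others had ratios there of 0.03 (mt-Co2), -0.69 (Hist1h2ap), -0.44 (mt-Atp6), 0.91 (Tmem254c) and -0.03 (Rpl10). Serpina1b, Hist1h2ap, Gm14288, Tmem254c, Gvin1 and Rpl10 belong to families with similar copies and are uncertain. Lep, the fat hormone leptin, had 17 counts in replicate 1 and 203 in replicate 2, a scaled 3.72-fold (95% counting interval 2.26 to 6.51).

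Of 153 named genes 119 had several annotated transcripts, and 110 had values in each table. The same transcript was the most abundant in both libraries for 97 of the 110 in the first table, and in both libraries and both tables for 71. It held a median of 77.2% of the gene's TPM. In the first table Cyp11a1-201 held 97.1% ± 1.07 (SD, n = 2) and Cyp21a1-201 95.8% ± 0.629. The second table gave them 92.19% ± 8.803 and 94.81% ± 3.896. For Star the leading transcript in the first table was Star-201 in replicate 1, at 61.8%, and Star-202 in replicate 2, at 53.8%, while in the second table Star-202 led in both, at 58.25% and 61.58%. Spike-ins held 0.473% of counts in replicate 1 (95% exact interval 0.470 to 0.476) and 0.797% in replicate 2 (0.7941 to 0.8001). Nuclear coding counts per spike-in count were 76.9 and 83.0, a ratio of 1.08 between the libraries, while all annotated counts per spike-in count were 210 and 124.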

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

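The alternatives with coding TPM, with protein-coding genes alone (nuclear ones other than Lars2 for the chi-square) and with both quantifications required were chosen only after the data were seen. Of 188 list levels under an alternative 119 stayed within 1 SD of the value reported and 69 moved. The 135 list ratios under an alternative leave out total counts. They cover DESeq2 size factors, spike-in counts, a prior of 5 counts, posterior mean counts and the second quantification. Of these 135, 128 shifted from the value reported by no more than 0.5 times the width of the middle 95% of random lists, and 7 moved. In 2 of the 135 the list changed sides of that range: the erythroid and abundant non-coding RNA lists lay outside it in the second quantification only. This count was added after the data were seen. A change of scaling shifts the random lists along with the list and so hardly moves a percentile. On the coding TPM scale, where values are higher by construction, 10 of the 27 lists had more members detected in both libraries and 0 had fewer: the interferon response list had 8 of 8, the X-zone 4 of 4 and the chromaffin cell list 18 of 18. On total counts, whose list directions were counted only after the data were seen, 12 of 27 list medians had another sign than under TMM, among them 6 of the 9 outside the random lists. On spike-in counts it was 4 of 27 and none of the 9, and none of the 9 changed sign with DESeq2 size factors, a prior of 5 counts, posterior mean counts or the second quantification. The number of genes detected in both libraries lay between 13267 and 18279 under the alternatives, and in a single library between 12705 and 13992. The correlation lay between 0.9156 and 0.9842. Levels without either replicate equal the value of the other one, so with 2 libraries they lie within 1 SD by construction. No paired analysis was possible because there is 1 group. Most members of the lymphocyte, kidney, exocrine pancreas and Y-linked lists had few counts, so that the ratios of these lists rest on few reads. Except where a rescaling sets the shift, the cause was not tested.

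Median list levels in coding TPM, which are higher by construction, were steroidogenic core 1617, zona glomerulosa 80.05, zona fasciculata 1105, X-zone 135.9, chromaffin cell 46.27, capsule and fibroblast 47.76, endothelium 54.49, Schwann and sustentacular 2.48, macrophage 18.24, lymphocyte 0.3184, erythroid 1949, adipocyte 231, kidney 0.08731, liver 53.7, exocrine pancreas 0.1182, immediate early and heat shock 27.49, circadian clock 40.81, cholesterol synthesis 156.5, proliferation 20.51, interferon response 7.219, maternally expressed imprinted 84.25, paternally expressed imprinted 30.72, X-inactivation 128.7, Y-linked 0.00739, abundant non-coding RNA 9812, mitochondrially encoded 17100, housekeeping 1116.

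In the second quantification median TPM was steroidogenic core 596.5, zona glomerulosa 32.08, zona fasciculata 426.5, X-zone 65.06, capsule and fibroblast 18.63, endothelium 29.63, Schwann and sustentacular 1.393, macrophage 7.765, lymphocyte 0.3342, adipocyte 124.9, exocrine pancreas 0.197, immediate early and heat shock 9.029, circadian clock 16.67, cholesterol synthesis 61.15, proliferation 7.626, maternally expressed imprinted 31.74, paternally expressed imprinted 14.01, Y-linked 0.2576, abundant non-coding RNA 131.7, housekeeping 729.6.

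After rescaling without mitochondrial genes, spike-ins and tRNA the medians were steroidogenic core 564.3, zona glomerulosa 28.09, zona fasciculata 374.6, Schwann and sustentacular 0.8512, erythroid 674.9, adipocyte 80.63, immediate early and heat shock 9.402, cholesterol synthesis 54.38, proliferation 7.021, X-inactivation 44.67, housekeeping 392.6. Posterior mean TPM gave Schwann and sustentacular 0.95, lymphocyte 0.4, kidney 0.225, exocrine pancreas 0.21, Y-linked 0.285, mitochondrially encoded 3976. In FPKM the medians were zona fasciculata 250.3, Schwann and sustentacular 0.57, immediate early and heat shock 6.33, proliferation 4.732, mitochondrially encoded 3934.

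Against 152 genes 2-fold apart under the settings reported, total counts gave 4168, a minimum of 10 counts 938, no minimum 5012, protein-coding genes alone 81 and both quantifications together 73. The list ratio of chromaffin cells was 0.383 on spike-in counts and that of cholesterol synthesis -0.153. With a prior of 5 counts the ratio was -5.777 for liver and 0.178 for exocrine pancreas, against -6.99 and 0.73 with a prior of 1. The second quantification gave -0.041 for exocrine pancreas, -0.191 for Y-linked and -0.547 for abundant non-coding RNA. Spike-ins held 0.7399% and 1.113% of TPM. The leading transcript held 72.69% in the second table, against 77.25%.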

Other observations

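The tests of the read assignment explanations, of the immediate early genes and of leakage in like amounts were chosen only after the result was seen, as were the genes named in this part that lie outside the rule for named genes. A group of 2 is too small for a test of outliers.

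Counts of some RNAs depended on the quantification. Rn7sk had 160766 and 393978 counts in the first and 12204 and 2 counts in the second. Length minus effective length was 99.0 nt in the first and 292.0 and 334.1 nt in the second. AA474408, which is not a short RNA, had 20 and 67 counts in the first and 356753 and 1640 in the second.

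After TMM scaling, replicate 1 had higher counts on Gm42418 (73.7-fold), Lars2 (672-fold) and CT010467.1 (43.6-fold). Before scaling the counts were 4687260 and 204216 for Gm42418, 532857 and 2548 for Lars2, and 1439 and 106 for CT010467.1. Gm26917, which lies beside CT010467.1 on chromosome 17, changed little (1.16-fold after scaling, with 2.05% and 3.25% of counts). Against an assignment error particular to the first quantification, the second gave Gm42418 5862010 and 287245 counts, 63.4-fold higher in replicate 1 after TMM scaling. An error that both quantifications share would not show in this comparison. Lars2 was not part of that test. The second quantification gave it 1716751 and 5988 counts, 891-fold higher in replicate 1 after scaling, so its count there differed from the first. Against higher expression of mitochondrial protein synthesis genes, the median log2 ratio of 16 other mitochondrial aminoacyl-tRNA synthetases was 0.136 (95% bootstrap interval -0.044 to 0.226). Ribosomal RNA left after depletion stays open for the set. All 3 of Gm42418, Lars2 and AA474408 met the criterion of a shared 31-mer. However, Lars2 and AA474408 shared 26 with each other and 0 with annotated ribosomal RNA. After scaling, AA474408 was 676-fold higher in replicate 1 in the second quantification, while its fold in the first was 0.959. Gm42418 lies within CT010467.1, so its 1735 shared 31-mers of 1801 follow from its position. Its sequence is thus mostly that of an annotated ribosomal RNA gene, and its reads need not come from a separate gene. The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 were also higher in replicate 1 after TMM scaling, 4.66-fold and 3.09-fold. The criterion was too wide to decide, and no biological explanation was tested beyond the synthetases.

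Liver transcripts stood out in replicate 1. Of 27 further liver genes, a list written before their values were seen, 23 (85.2%) were at least 2-fold higher in replicate 1, which is consistent with liver tissue or RNA carried into that library, with Alb at 141 and 3.47 TPM. The exceptions Apoc1, Hp, Itih2 and Fetub had 4405, 1009, 282 and 1054 counts in replicate 2, and reads from other cells could hide a liver share of them. Against an assignment error particular to the first quantification, the second gave Alb 4566 and 74 counts, 188-fold higher in replicate 1 after TMM scaling. An error shared by both would not show here either. Against reads leaking in like amounts from libraries of liver, skeletal muscle, heart, kidney and pancreas, the median counts of the genes of the other tissues in replicate 1 had upper 95% bounds of 5.23% or less of the liver list median of 223 counts. Reads leaking from libraries of several tissues in unequal amounts, most of them from liver, stay open, since 4 of 12 skeletal muscle, heart and brain genes were 2-fold higher in replicate 1, each of the 4 with 7 counts or fewer in either library, and no biological difference between the glands was tested.

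Heat shock factor targets lay apart between the libraries, while clock genes went both ways (log2 ratio of Arntl -1.47 and of Per3 0.73), so that the median of their list decides nothing. The median log2 ratio of 12 further heat shock factor targets was -0.592, at percentile 0 of random lists (95% of which lay between -0.153 and 0.107), as a heat shock response higher in replicate 1 would give. Whether such a response arose in the animal or during collection was not tested. Against an acute handling response, the median of 11 immediate early genes was 0.126 (95% bootstrap interval -0.094 to 0.424). These are the immediate early and heat shock list, with a reported median of 0.09, without Hspa1a and Hspa1b. The outcome could therefore be foreseen, and the evidence is weak. The members went both ways, from -0.54 for Egr1 to 0.87 for Atf3, which had 2 and 13 counts. A different clock phase at collection stays open, as the 4 further clock outputs in phase with Dbp had a median of 0.161, at percentile 78.86.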
